A study of Homo sapiens with 6 samples.

How the data were processed

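RNA was measured by sequencing in 6 libraries of HTR-8/SVneo cells, 3 with a SIGLEC6 expression vector and 3 with the empty vector. Cells were selected with puromycin, total RNA was extracted and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols. The deposited table holds whole-number read counts per gene symbol, 1 column per library, with no normalization. Its columns name the negative control shNC, whereas the labels describe an empty vector, and columns were matched to libraries by group and replicate number in the titles. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq, Bowtie2, StringTie and SAMtools, with no versions, roles or order. They also name the mouse build mm10, although the samples are human and the rows are human gene symbols. The human build used is not given in the sources used here, so no coordinates are printed. The strand setting and the treatment of reads that match several genes are not given either. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain.

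Of 19470 rows, 19085 carried a current human symbol and 19078 were found in RefSeq annotation of GRCh38.p14, which was used only for names and neighbours. Transcript length and GC content were those of the longest protein-coding GENCODE transcript of each gene. Length and GC were available for 12593 of the 12738 tested genes. Genes that failed the low-count filter were left out of the library sizes used in the edgeR and limma-voom fits and for mean CPM values. Total counts ranged from 34919791 to 37781224 per library, and 3 counts in a library correspond to between 0.0794 and 0.0859 CPM. TMM factors ranged from 0.9869 to 1.011, and the 10 most abundant genes took between 5.77% and 6.05% of counts. Reads without molecular identifiers are not independent molecules, so limits derived from counts cover counting error only. Pairs of replicates within a group were compared gene by gene with a chi-square statistic at a summed count of at least 50. Its median lay between 1.72 and 2.23 where sampling noise alone gives 0.455, so no pair was a copy of 1 library.

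The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM normalization, the default low-count filter, a design with group as its only term and Benjamini-Hochberg adjustment over the tested genes at 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values were computed from the counts of tested genes with TMM-scaled library sizes and are given as mean ± SD of 3 libraries. GPR20 did not pass the filter and was tested in the fit without it, as fixed before the data were examined. Where all control libraries had 0 counts, the fold was computed against 3 counts over the whole control group. Across 26 gene lists, 25 had members to test, and the list of mitochondrial DNA genes had none. Lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01 (limma 3.58.1), and counts of members past the threshold were given over all genes and adjusted over the list alone.

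The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named SIGLEC6 and GPR20, then the 10 largest increases and 10 largest decreases among genes past an adjusted p of 0.05 with a mean of at least 5 CPM and no overlap between groups. It then named up to 3 members of each list with the smallest p among those past the threshold, or, where none passed, the 2 with the highest mean CPM. The lists cover nuclear-encoded oxidative phosphorylation subunits, mitochondrial dynamics, mitochondrial biogenesis, antioxidant genes, glycolysis, hypoxia, apoptosis and stress responses. They also cover matrix proteases and invasion, 3 trophoblast types, preeclampsia-associated genes, and mesenchymal, endothelial and leukocyte markers. The remaining lists cover interferon and cytokine genes, S phase, mitosis, sterol synthesis, Siglec and cAMP signalling, ribosomal proteins, histones and immediate early genes.

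Alternatives were median-ratio, upper-quartile and library-size scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 (1.42.0), limma-voom, the replicate number as a block, leaving out each library in turn, an adjusted p of 0.01 and an absolute log2 fold change of at least 1. For lists they were camera with an estimated correlation, fry, the block, median-ratio scaling, the stricter filter and leaving out libraries. Length and GC offsets and lists without SIGLEC6 were added after the data were seen. The pipeline was tested on simulated data with the real genes, means and library sizes. In the comparison of overexpression with control over 12738 genes, edgeR recovered 30% of 50 genes changed 1.15-fold, 62% of 50 changed 1.25-fold, 80% of 50 changed 1.5-fold and 96% of 50 changed 2-fold. It also called 7 unchanged genes, 4.96% of all calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.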

Results

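HTR-8/SVneo is an established human trophoblast line derived from early placental tissue and widely used as a model of extravillous trophoblast. By the labels, the cells carried a vector with a CMV promoter, the fluorescent protein ZsGreen1 and a puromycin resistance gene. It held SIGLEC6 or was empty, and the cells were selected with puromycin. The count columns name the controls shNC, so the empty vector rests on the labels alone. Gene counts were available for 3 libraries of SIGLEC6-overexpressing cells and 3 libraries of empty-vector cells. Total counts were 35708119, 34919791 and 36785734 in overexpression replicates 1, 2 and 3, and 35470443, 37781224 and 35293317 in control replicates 1, 2 and 3. Of 19470 genes in the table, 12738 passed the low-count filter and 3892 had no count in any library. Spearman correlations between libraries, taken across genes, ranged from 0.9894 to 0.991, and the biological coefficient of variation was 5.11%. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

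The first comparison asked whether the vector raised its target. SIGLEC6, a sialic acid-binding immunoglobulin-like lectin of the placenta, was the gene with the largest change. It had 73411, 73155 and 77966 counts in overexpression replicates 1, 2 and 3 and 27, 37 and 34 counts in the control replicates. In CPM, counts scaled to library size, the level was 2107 ± 36.95 (SD, n = 3) with overexpression and 0.894 ± 0.1195 CPM (SD, n = 3) with empty vector. The log2 fold change was 11.19 (SE 0.0597; edgeR adjusted p = 1.47e-43), and the counts of each library matched its label. SIGLEC6 took between 0.206% and 0.212% of all counts in the overexpression libraries. Counts per gene do not separate vector transcripts from the cells' own SIGLEC6. The 13 other Siglec genes in the table, CD22 and CD33 included, had at most 13 counts in any library and none passed the low-count filter.

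GPR20, an orphan G protein-coupled receptor named in the series title as a link between SIGLEC6 and mitochondrial function, was detected in the overexpression libraries and in none of the controls. It had 14, 6 and 8 counts in overexpression replicates 1, 2 and 3 and 0 in each control replicate, or 28 of 107413644 against 0 of 108544984 total counts. The level was 0.262 ± 0.116 CPM (SD, n = 3) with overexpression. Pooled over the group, it was 9.58 times the limit that 3 counts over the whole control group would give, 0.0274 CPM. That limit covers counting error only, and the ratio leaves out the spread of the overexpression libraries, so it is no lower bound. GPR20 fell short of the low-count filter and was tested in a fit of 15578 genes without that filter, in which it passed the threshold (edgeR adjusted p = 0.0215). DESeq2 (adjusted p = 0.0275) and limma-voom (adjusted p = 0.0257) gave the same call. The call did not survive the loss of most single libraries. The edgeR adjusted p was 0.139 without overexpression replicate 1, 0.0398 without replicate 2 and 0.0728 without replicate 3, and 0.0931, 0.175 and 0.147 without control replicates 1, 2 and 3.

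**Figure D1:**
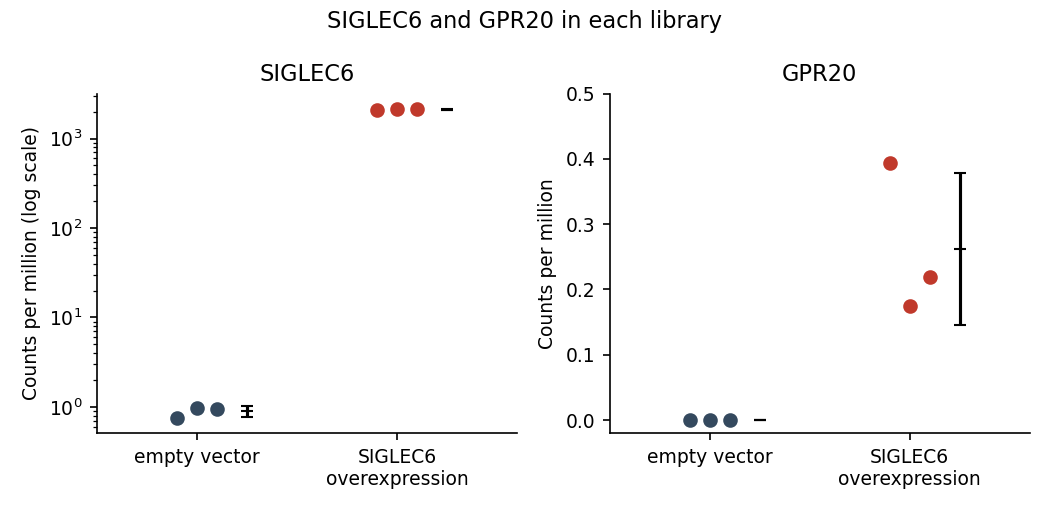
CPM of SIGLEC6 (left, log scale) and GPR20 (right, linear scale) in each library; points are single libraries, and the bars beside them give the mean and SD of 3. SIGLEC6 lies near 2107 CPM with overexpression and 0.894 CPM with empty vector, and GPR20 lies at 0 in all 3 controls.

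Across all genes, SIGLEC6 overexpression went with changes in a small set of transcripts, most of them modest. In edgeR's quasi-likelihood test 112 genes passed an adjusted p of 0.05, 70 higher and 42 lower with overexpression. Of these, 96 changed by less than 1.5-fold and the median absolute log2 fold change was 0.262. The 8 genes with an absolute log2 fold change of at least 1, named here after their values were seen, were SIGLEC6, MAGED4B, VAMP7, TBC1D3 and ABCC9 among the increases and PSG8, OTUD7A and GPNMB among the decreases. MAGED4B, VAMP7, TBC1D3 and PSG8 have near-identical copies or a further listing in the table, so their counts are uncertain, and MAGED4B had 520 counts in overexpression replicate 1 and at most 29 in any other library. Values of overexpression and control libraries did not overlap for 110 of the 112 genes, MAGED4B and VAMP7 being the exceptions. Over all tested genes 2051 (16.1%) did not overlap, where chance gives 10%. The count rested on the libraries used, with 69 genes without overexpression replicate 2, 32 without overexpression replicate 3 and 47 without control replicate 3. The balance of directions rested on the scaling, with 34 higher and 64 lower when libraries were scaled by total count only, and with 307 higher and 81 lower under length and GC offsets chosen after the data were seen.

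Among the 10 largest increases named by the fixed rule, ABI3BP and IGFBP3 had the smallest p-values after SIGLEC6. ABI3BP, an extracellular matrix protein, rose from 305 ± 0.72 to 407 ± 17.8 CPM (SD, n = 3; log2 fold change 0.41, SE 0.0357, edgeR adjusted p = 7.82e-09). IGFBP3, which binds insulin-like growth factors, rose from 69.3 ± 1.35 to 93.9 ± 0.62 CPM (SD, n = 3; log2 fold change 0.44, SE 0.0439, edgeR adjusted p = 1.97e-07). The growth factor gene FGF5 (log2 fold change 0.51), the pentraxin gene PTX3 (0.53), the sphingosine 1-phosphate receptor gene S1PR1 (0.61) and PREX1 (0.48), an exchange factor for Rac, also rose. KRTAP2-3, a keratin-associated protein (0.94), IGFN1 (0.68) and AKR1C1, an enzyme that inactivates progesterone (0.51), completed the 10 largest increases with SIGLEC6. KRTAP2-3 and AKR1C1 have near-identical relatives, KRTAP2-4 and AKR1C2, with which reads can be shared, so these 2 values are uncertain.

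The largest decrease under the rule was in GPNMB, a transmembrane glycoprotein, which fell from 10.4 ± 0.45 to 4.53 ± 0.51 CPM (SD, n = 3; log2 fold change -1.20, SE 0.132, edgeR adjusted p = 1.3e-06). CEBPD, a transcription factor of the C/EBP family, fell from 74.2 ± 3.64 to 53.2 ± 5.02 CPM (SD, n = 3; log2 fold change -0.48, SE 0.0567, edgeR adjusted p = 4.83e-06). The laminin chain gene LAMA3 (log2 fold change -0.75), the complement gene C3 (-0.58), the hedgehog pathway transcription factor gene GLI1 (-0.56) and BMP5 (-0.54), of the bone morphogenetic protein family, fell as well. MGARP (-0.55), a protein located at mitochondria, the receptor-type phosphatase gene PTPRQ (-0.58), SAMD14 (-0.69) and the zinc finger gene ZNF862 (-0.56) completed the 10 largest decreases. Of these 19 genes other than SIGLEC6, 6 kept their call in all alternatives tried for named genes: KRTAP2-3, IGFN1, IGFBP3, ABI3BP, GPNMB and CEBPD. The other 13 lost it in at least 1 fit without a library, 7, 6 and 12 of them without overexpression replicates 1, 2 and 3 and 5, 3 and 10 without control replicates 1, 2 and 3, with adjusted p up to 0.206 in edgeR. ZNF862 also lost its call in limma-voom.

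**Figure D2:**
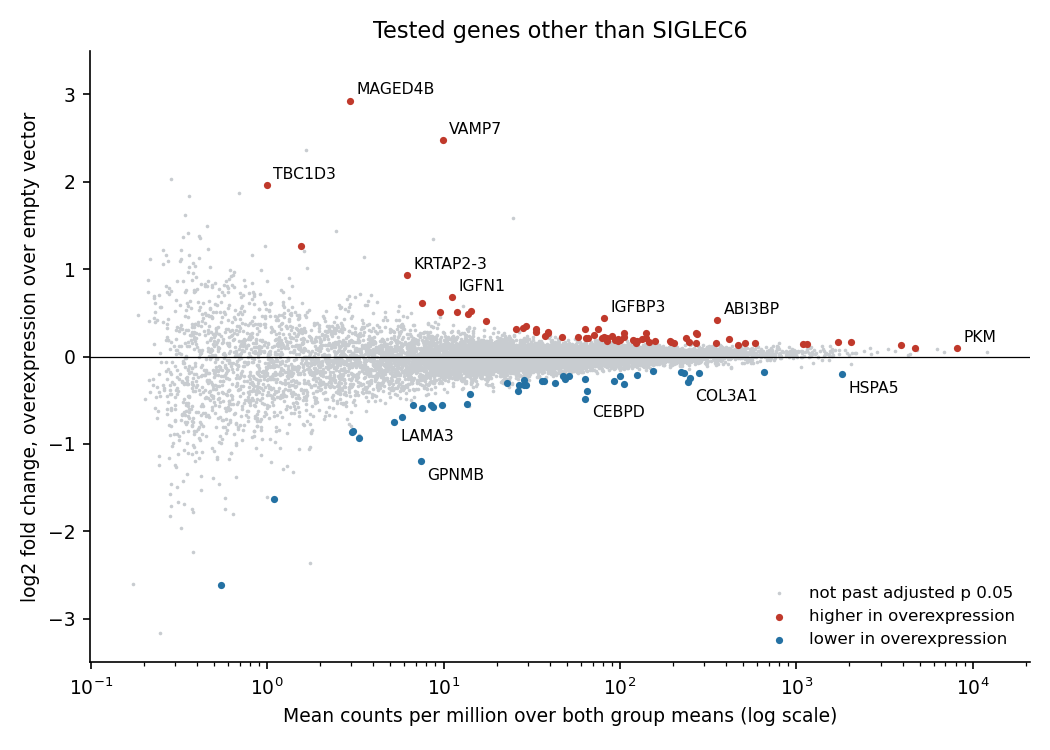
Log2 fold change of overexpression over empty vector against mean CPM (log scale) for the tested genes other than SIGLEC6, 1 point per gene; colored points are genes past an edgeR adjusted p of 0.05. Most of the colored points lie within 1.5-fold, and MAGED4B, VAMP7 and TBC1D3 stand at the top.

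**Figure D3:**
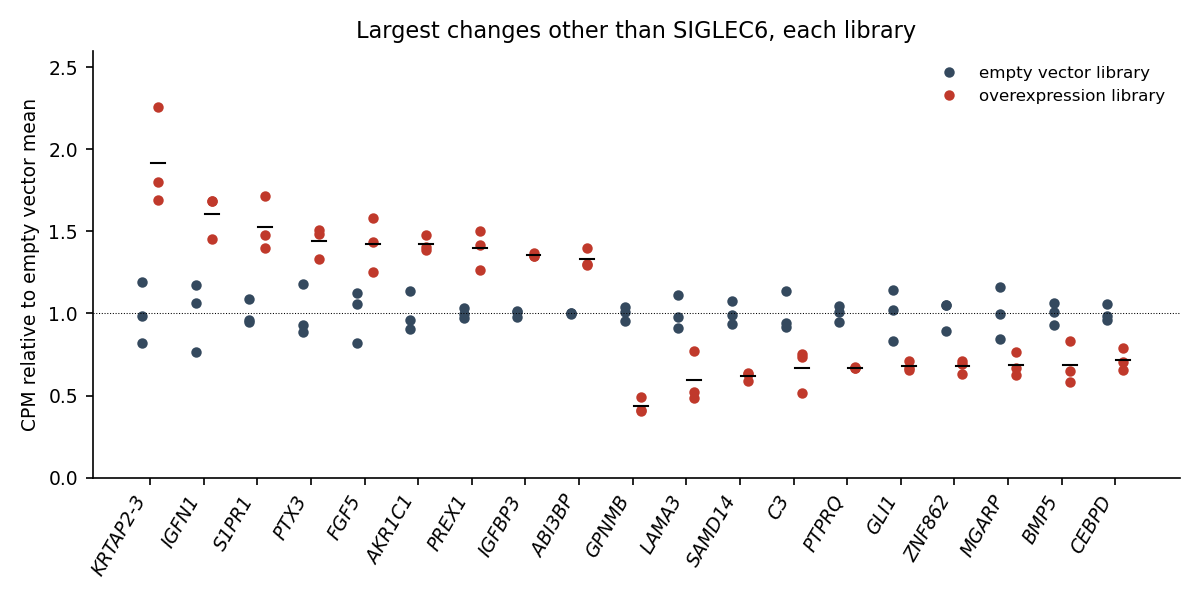
CPM of the named genes with the largest changes, divided by the mean of the 3 empty-vector libraries, with 1 point per library and a bar at the overexpression mean. The 2 groups do not overlap for any of these 19 genes, as the rule that named them required.

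Genes of mitochondrial respiration were the next question, since the series title names mitochondrial dysfunction. None of the 76 nuclear-encoded subunits of oxidative phosphorylation passed the test in edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7, and DESeq2 and limma-voom called 0. Over all 12738 tested genes 1429 had an unadjusted p under 0.05 in edgeR, the share to set beside this and the later unadjusted counts. The median log2 fold change was 0.0315, with 50 of 76 values above 0, against 0.00874 and 40 of 76 with library-size scaling, and ATP5F1B, the ATP synthase beta subunit, was at 951 ± 25.3 CPM with empty vector and 984 ± 38.2 CPM with overexpression (SD, n = 3). NDUFB9, of complex I, had a log2 fold change of 0.079 (SE 0.0386; edgeR adjusted p = 0.442). The 13 protein-coding genes of mitochondrial DNA had no rows here and were not analysed. Of the 24 tested genes of mitochondrial fission, fusion and mitophagy, edgeR, DESeq2 and limma-voom called 0, with 2 at an unadjusted p under 0.05 in edgeR and 0 adjusted over the list alone. FKBP8 was at log2 fold change -0.057 and SQSTM1, an autophagy receptor, at 0.096. Of the 22 tested genes of mitochondrial biogenesis and mtDNA maintenance, edgeR and limma-voom called 0, with 5 at an unadjusted p under 0.05 in edgeR. HSPD1, the mitochondrial chaperonin, was past the threshold adjusted over the list alone, in DESeq2 and in edgeR without the low-count filter (log2 fold change 0.12, SE 0.0336), and HSPA9 was at 0.082.

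Metabolic and antioxidant genes moved little. PKM, the last ATP-producing enzyme of glycolysis, rose from 7891 ± 91.5 to 8457 ± 90.0 CPM (SD, n = 3; log2 fold change 0.10, SE 0.0227, edgeR adjusted p = 0.0233). The call was lost with upper-quartile or library-size scaling and with the replicate number as a block. It was also lost without overexpression replicate 2 or 3 or control replicate 2 or 3. The log2 fold change stayed between 0.077 and 0.11 in all alternatives. PKM was the 1 of 24 glycolysis genes past the threshold over all genes in edgeR and limma-voom. HK1, hexokinase 1, named after its value was seen, was the other of 2 that passed adjusted over the list alone and in DESeq2. Of 25 tested antioxidant and NRF2 target genes edgeR and limma-voom called 0, with 4 at an unadjusted p under 0.05 in edgeR. TXNRD1, thioredoxin reductase, passed adjusted over the list alone and in DESeq2 (log2 fold change 0.11, SE 0.0328), and the peroxiredoxin gene PRDX1 was at 0.066 (SE 0.0423). Of 23 tested sterol synthesis genes, edgeR, DESeq2 and limma-voom called 0, with 3 at an unadjusted p under 0.05 in edgeR and 0 adjusted over the list alone. LDLR, the low-density lipoprotein receptor, was at log2 fold change -0.041 and DHCR24 at -0.052.

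Hypoxia-response genes went both ways. NDRG1 fell (log2 fold change -0.24, SE 0.0383, edgeR adjusted p = 0.000464), as did the transcription factor gene BHLHE40 (-0.28, SE 0.0487), while LOX, which crosslinks collagen, rose (0.22, SE 0.0405). ADM, adrenomedullin, rose too (0.25, SE 0.0478) and is named after its value was seen, to complete the 2 higher and 2 lower of 21 tested. Adjusted over the list alone, 2 were higher and 3 lower. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 1954 ± 78.0 to 1698 ± 31.1 CPM (SD, n = 3; log2 fold change -0.20, SE 0.0304, edgeR adjusted p = 0.000222). It was the 1 of 24 tested genes of the integrated stress and unfolded protein responses past the threshold, with 2 lower adjusted over the list alone. CDKN1A, the p21 inhibitor of the cell cycle, fell (-0.18, SE 0.0385, edgeR adjusted p = 0.0132) and was the 1 of 30 apoptosis and p53 target genes past the threshold, over all genes and adjusted over the list alone.

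Trophoblast markers showed a few small increases. PEG10, an imprinted placental gene (log2 fold change 0.24, SE 0.0459, edgeR adjusted p = 0.00616), and ITGA6, the laminin-binding integrin alpha 6 (0.22, SE 0.049, edgeR adjusted p = 0.0233), rose among 13 tested villous cytotrophoblast markers. Among 10 tested syncytiotrophoblast markers TFPI2, a protease inhibitor, rose (0.31, SE 0.0543, edgeR adjusted p = 0.00182), as did PSG4 (0.23, SE 0.0571, edgeR adjusted p = 0.0449), whose reads can be shared with other pregnancy-specific glycoprotein genes. The PSG4 call was lost in DESeq2 and limma-voom, and with upper-quartile or library-size scaling. PSG8, of the same family but outside the marker list, fell (-2.62, SE 0.576, edgeR adjusted p = 0.0214) at group means under 1 CPM. In both lists the same 2 members were higher and 0 lower adjusted over the list alone. Of 10 tested extravillous markers edgeR, DESeq2 and limma-voom called 0, with 3 at an unadjusted p under 0.05 in edgeR and 1 lower, MMP15 (-0.15, SE 0.0441), adjusted over the list alone. MMP15 was also past the threshold over all genes in edgeR without the low-count filter (adjusted p = 0.0471). The fibronectin receptor subunit ITGA5 was at -0.0045. ITGA6 was also the 1 of 24 tested genes of matrix proteases and invasion past the threshold, with 5 higher and 1 lower adjusted over the list alone. In the 17 tested preeclampsia-associated placental genes SIGLEC6 was the 1 higher and NDRG1 the 1 lower, over all genes and adjusted over the list alone.

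Markers of other cell types gave few calls over all genes. COL3A1, a fibrillar collagen chain, fell from 269 ± 1.39 to 220 ± 4.12 CPM (SD, n = 3; log2 fold change -0.29, SE 0.0351, edgeR adjusted p = 7.14e-06) and was the 1 of 22 tested mesenchymal and stromal markers past the threshold. Adjusted over the list alone 1 was higher and 3 were lower, and 7 of the 22 had an unadjusted p under 0.05 in edgeR. Most of this list was expressed in these cells, with 22 of 26 members past the low-count filter. CD68, a lysosomal glycoprotein used as a macrophage marker, rose (0.19, SE 0.0438, edgeR adjusted p = 0.0222), and it was 1 of only 2 leukocyte markers of 19 that were tested, with 1 higher adjusted over the list alone. Of 4 tested endothelial markers edgeR, DESeq2 and limma-voom called 0, with 1 at an unadjusted p under 0.05 in edgeR and 1 higher adjusted over the list alone. EGFL7 and SOX18 were at log2 fold changes of 0.015 and 0.021, both below 0 with library-size scaling.

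Immediate early genes split. The transcription factor gene EGR1 fell (log2 fold change -0.25, SE 0.0552, edgeR adjusted p = 0.0206), while the phosphatase gene DUSP1 (0.21, SE 0.0469, edgeR adjusted p = 0.0222) and JUN (0.17, SE 0.0417, edgeR adjusted p = 0.0333) rose. These were the 2 higher and 1 lower of 22 tested, with 4 higher and 2 lower adjusted over the list alone. In the list of Siglec, Gi-coupled receptor and cAMP signalling genes SIGLEC6 was the 1 of 22 tested genes past the threshold, with 1 higher and 2 lower adjusted over the list alone. Of the 15 list members other than SIGLEC6 named as past the threshold under the rule, NDRG1, BHLHE40, LOX, HSPA5, TFPI2 and COL3A1 kept the call in all alternatives. The other 9 lost it in at least 1 fit without a library, 3, 7 and 8 of them without overexpression replicates 1, 2 and 3 and 3, 4 and 8 without control replicates 1, 2 and 3. With library-size scaling the calls of PKM, ITGA6, PSG4, CD68, DUSP1 and JUN were lost. With upper-quartile scaling those of PKM, PSG4 and JUN were lost, and PSG4 was also lost in DESeq2 and limma-voom.

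The lists for S phase, mitosis, ribosomal proteins, histones, interferon-stimulated genes and cytokines held no call over all genes in edgeR with the default filter. For DNA replication and S phase, 0 of 26 passed in edgeR, DESeq2 and limma-voom, with 2 at an unadjusted p under 0.05 in edgeR, and the helicase genes MCM4 and MCM7 were at log2 fold changes of 0.033 and 0.013. For mitosis 0 of 26 passed in the 3 tools and 0 had an unadjusted p under 0.05, with TPX2 at 0.038 and MKI67 at 0.0096. MCM7 and MKI67 were below 0 with library-size scaling. For cytosolic ribosomal proteins 0 of 65 passed in the 3 tools, with 6 at an unadjusted p under 0.05 in edgeR, and RPLP0 and RPL8 were at 0.036 and 0.040. For replication-dependent histones, whose near-identical copies can share reads, 0 of 19 tested passed in the 3 tools, with 1 at an unadjusted p under 0.05 in edgeR, and H2BC12 and H2AC6 were at 0.052 and -0.040. For interferon-stimulated genes 0 of 29 tested passed in the 3 tools, with 2 at an unadjusted p under 0.05 in edgeR, and STAT1 and OAS3 were at 0.034 and -0.087. None of these 5 lists had a member past the threshold adjusted over the list alone. For inflammatory cytokines and NF-kB targets edgeR and limma-voom called 0 of 19 tested, with 4 at an unadjusted p under 0.05 in edgeR. TNFAIP2, also named after its value was seen, was lower adjusted over the list alone and in DESeq2 (-0.79, SE 0.212), while NFKB2 and ICAM1 were at -0.054 and -0.13.

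Tested as sets for a shift in 1 direction, the lists did not stand apart from other genes. With camera at a preset correlation of 0.01, 0 of 25 lists passed an adjusted p of 0.05 and 3 had an unadjusted p under 0.05. These were cytosolic ribosomal proteins toward higher values (adjusted p = 0.119), syncytiotrophoblast markers toward higher values (adjusted p = 0.178) and the integrated stress and unfolded protein responses toward lower values (adjusted p = 0.178). With a correlation estimated for each list 0 passed, adjusted or unadjusted. With fry, which tests whether members move on balance in 1 direction, 2 lists passed and 4 had an unadjusted p under 0.05. The 2 were the preeclampsia and Siglec signalling lists (adjusted p = 0.00221 for each), which both hold SIGLEC6 itself, and 0 passed when SIGLEC6 was taken out. Fry's mixed test counts changes in either direction and does not compare a list with other genes. Its unadjusted p was 3.14e-06 for matrix proteases and invasion, 0.000301 for mesenchymal markers, 0.000642 for immediate early genes and 0.798 for mitosis. At an unadjusted edgeR p under 0.05 were 8 of 24 matrix protease, 7 of 22 immediate early and 6 of 21 hypoxia genes. Over all genes it was 1429 of 12738, and this excess was not tested. Leaving out single libraries changed 2 lists in camera. Ribosomal proteins passed without overexpression replicate 1 (adjusted p = 0.00462), overexpression replicate 3 (adjusted p = 0.00032) and control replicate 1 (adjusted p = 8.09e-06), and oxidative phosphorylation passed without overexpression replicate 3 (adjusted p = 0.00763) and control replicate 1 (adjusted p = 0.00471), all toward higher values. Median and mean differed in sign in 2 lists without SIGLEC6: mesenchymal markers had a median of -0.0388 and a mean of 0.00958 log2 fold change, and cytokine and NF-kB targets a median of 0.0444 and a mean of -0.00141, with camera pointing lower for both. The Siglec signalling list had a median of 0.00315 and, without SIGLEC6, a mean of -0.0284, with camera pointing higher.

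**Figure D4:**
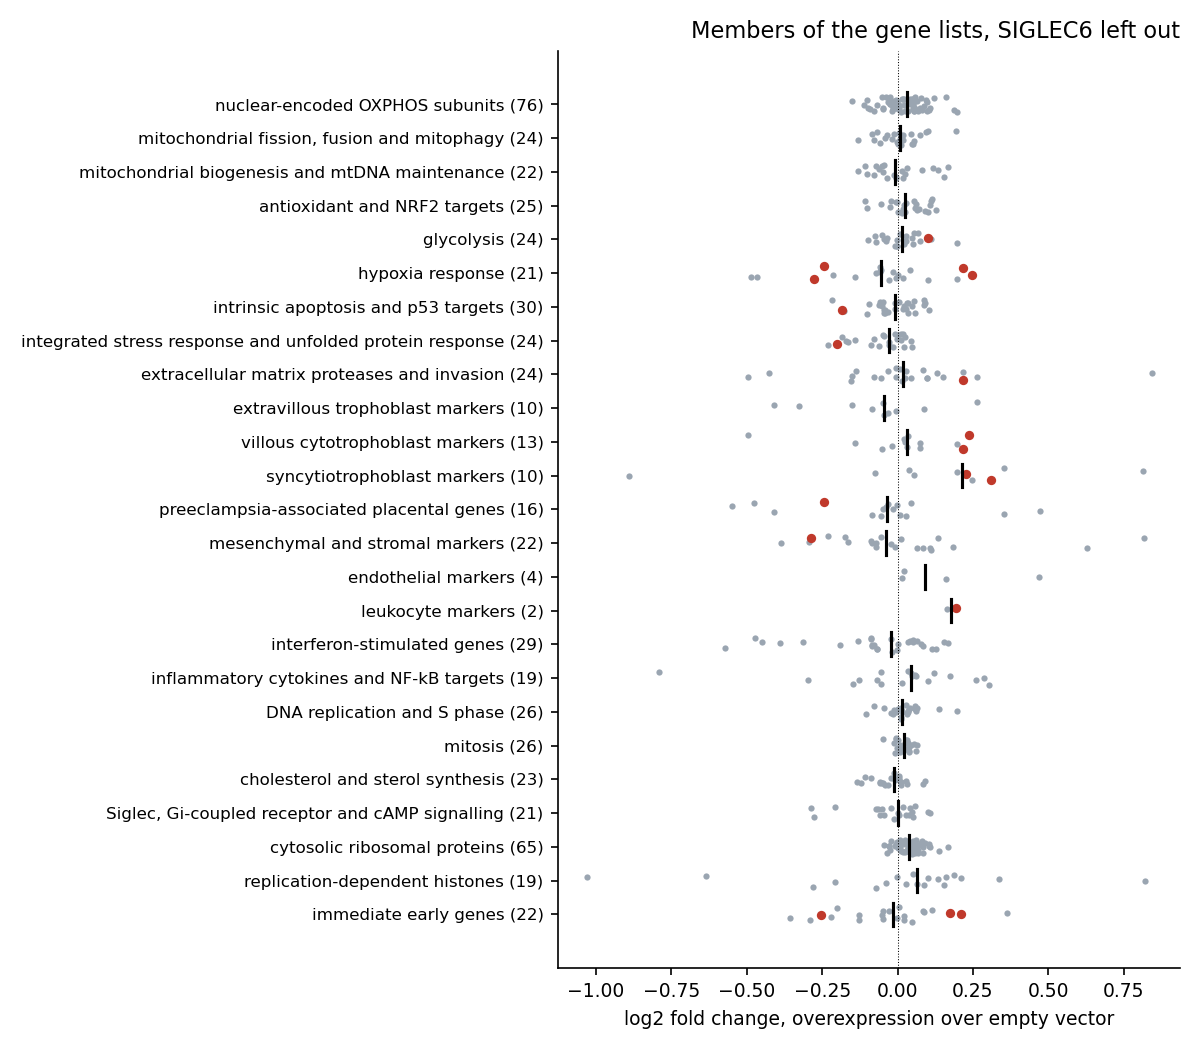
Log2 fold change of overexpression over empty vector for each tested member of the 25 lists, SIGLEC6 left out, with list sizes in parentheses; red points passed an edgeR adjusted p of 0.05 over all genes and black bars are medians. The 76 oxidative phosphorylation subunits lie between -0.15 and 0.20 with none in red.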

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

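SIGLEC6 kept its direction and its call under all 14 alternatives, with log2 fold changes from 11.09 to 11.26. Of the 112 changed genes, 107 remained past the threshold with the length and GC offsets, which were chosen after seeing the data and called 388, and 112 remained without a low-count filter, which called 231. The stricter adjusted p of 0.01 left 42 genes and the fold limit 8. Fits with 1 library fewer called between 32 and 93, and 26 of the 112 genes were called in all 6. The remaining settings called between 98 and 153. The causes of these differences were not tested, apart from the stricter thresholds and the smaller number of libraries. Replicate numbers did not pair the samples: same-numbered libraries correlated at -0.021, -0.031 and 0.0057 in their deviations from group means, and none correlated best with its own number. With the replicate number as a block 150 genes were called, 109 of them among the 112, and GPR20 was at a log2 fold change of 6.24 and an adjusted p of 0.0957, no longer past the threshold. The block also ended the call of PKM and of no other named gene. GPR20 fits without a library gave 5.853 to 6.49, values that depend on the prior count and bound nothing, and the 1 CPM filter removed it and gave no value.

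For lists, the count of 0 became 2 with fry and between 0 and 2 without a library. With library-size scaling EGFL7 (-0.007845), SOX18 (-0.001552), MCM7 (-0.009713) and MKI67 (-0.01318) turned below 0, none past the threshold. Without single libraries the sign of ITGA5 (-0.01677 to 0.002522), EGFL7 (-0.01974 to 0.04427), SOX18 (-0.06471 to 0.1195), MCM7 (-0.001246 to 0.02096) and MKI67 (-0.04563 to 0.06084) was not fixed. The preeclampsia list turned higher with fry (adjusted p = 0.00221), and the Siglec signalling list turned lower without SIGLEC6 (adjusted p = 0.458 with camera, 0.32 with fry), both by the weight of SIGLEC6. The camera direction also turned without single libraries for lists of sterol synthesis (adjusted p 0.402 to 0.953), ribosomal proteins (8.09e-06 to 0.784), immediate early genes (0.67 to 0.871), cytokines (0.483 to 0.874), apoptosis (0.54 to 0.983), mitochondrial biogenesis (0.635 to 0.983), oxidative phosphorylation (0.00471 to 0.853) and Siglec signalling (0.698 to 0.983). The cause was not tested. At this depth simulated changes of up to 1.5-fold were recovered in part, and genes such as GPR20 rest on few counts.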

Other observations

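All gene families in this paragraph and the next were chosen after the values were seen, and 9 were tested. Their p-values come from the same values that led to the choice, so they describe these data and give no independent support. Cytosolic chaperones had log2 fold changes above 0 in 20 of 22 members under all 4 scalings, with HSPA8 (0.17, SE 0.0312, edgeR adjusted p = 0.00453) and HSP90AA1 (0.13, SE 0.0287, edgeR adjusted p = 0.0222) higher, 1 of them with library-size scaling. The family test passed with camera's preset correlation (adjusted p = 2.54e-05) and not with an estimated correlation (adjusted p = 0.383). HSPA5 of the endoplasmic reticulum went the other way, and 10 of 16 chaperones of that compartment were below 0, or 12 with upper-quartile and 15 with library-size scaling (adjusted p = 0.0322, and adjusted p = 0.435 with an estimated correlation). Of 29 actin and actin-binding genes 24 were above 0, or 22 with upper-quartile and library-size scaling (adjusted p = 0.00483, and adjusted p = 0.383 with an estimated correlation), with CORO1C, ACTG1 and TMSB10 higher and TMSB4X lower in edgeR. Upper-quartile and library-size scaling left 1 of those 3 increases. Mitochondrial ribosomal proteins had 56 of 76 members above 0, or 49 with library-size scaling, and 0 past the threshold in edgeR, DESeq2 and limma-voom, with 6 at an unadjusted p under 0.05 in edgeR (adjusted p = 0.00483 for the family, and adjusted p = 0.547 with an estimated correlation).

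Of 25 collagen genes 19 were below 0, with COL3A1 and COL5A2 (log2 fold change -0.18, SE 0.0313, edgeR adjusted p = 0.00184) lower; upper-quartile scaling, library-size scaling and limma-voom called 4 lower and DESeq2 3 (camera adjusted p = 0.00483, and adjusted p = 0.383 with an estimated correlation). Of 14 complement genes 12 were below 0 under all 4 scalings, and C3, C1R (-0.28, SE 0.0622) and C1S (-0.94, SE 0.21) were lower (camera adjusted p = 0.0134, and adjusted p = 0.383 with an estimated correlation). The C3 call was lost without overexpression replicate 1, 2 or 3 and without control replicate 1 or 3. C1S was at low levels, 4.37 CPM with empty vector and 2.28 CPM with overexpression. Integrin genes had ITGA6 and ITGA2 (0.32, SE 0.0778) higher of 15, both lost with library-size scaling and ITGA2 also in DESeq2 (camera adjusted p = 0.11, and adjusted p = 0.383 with an estimated correlation). Laminin genes had LAMA1 (0.21, SE 0.049) higher, a call lost with library-size scaling, and LAMA3 lower of 10 (adjusted p = 0.293, and adjusted p = 0.547 with an estimated correlation). Of 4 insulin-like growth factor binding proteins IGFBP3 was higher and IGFBP7 (-0.40, SE 0.0488, edgeR adjusted p = 7.14e-06) lower (adjusted p = 0.939, and adjusted p = 0.942 with an estimated correlation).

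Of the tests that follow, all but those of the splits of libraries for the 112 changed genes and of the neighbours of GPR20 were chosen after the result was seen. The first pattern is that the largest increases after SIGLEC6 were in MAGED4B, VAMP7 and TBC1D3, genes with near-identical copies. TBC1D3 had 77, 39 and 53 counts with overexpression and 15, 6 and 23 in controls, but its 11 copies summed did not pass (log2 fold change 0.225, SE 0.193, edgeR adjusted p = 0.718), in line with reads divided unevenly between copies. VAMP7 had 99, 796 and 902 counts with overexpression and 104, 115 and 111 in controls, in 1 of its 2 listings. The sum of both VAMP7 listings was not tested. Of 10 other genes listed in 2 copies, with both listings summed, 5 varied over 4 times within a group. Among other genes 182 of 5325 did (3.42%, Fisher's exact test, two-sided p = 1.1e-05). That test takes genes as independent, and genes counted in the same libraries may vary together, so its p-value may be too small. Unstable counting of such genes is a candidate explanation. MAGED4B had 520 counts in overexpression replicate 1 and between 18 and 29 in every other library, and the sum of MAGED4 and MAGED4B in that replicate was 9.32 times the highest other library, which argues against reads exchanged between the 2 copies. The cause of that 1 high library stays open, and no biological explanation was tested for these 3 genes.

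The second pattern is GPR20, seen in 3 of 3 overexpression libraries and in 0 of 3 controls. The pattern searched for was at least 6 counts in each library of 1 group and 0 in the other. The 6 is the lowest count of GPR20 itself, so GPR20 had to qualify in the real split. Toward overexpression 2 genes had this pattern, GPR20 and MLIP (named after its counts were seen). The other way 0 had it, and 0 had it in any of the other splits of the libraries. Chance at low counts stays open: among 2840 genes below the filter 4 were called in the real split and at most 1 in any other of the 10 splits, too few for a share under 0.05, and GPR20 kept its call in 1 of 6 fits without a library (edgeR adjusted p up to 0.175). The fit without the filter, from which the GPR20 call comes, was the more permissive. It called 231 genes in the real split and between 2 and 23 in the others, against 112 and at most 5 with the filter. Reads running in from a neighbour were argued against by SLC45A4 (log2 fold change -0.0436, SE 0.0495) and PTP4A3 (-0.031, SE 0.0688), the adjacent protein-coding genes, neither past the threshold and the larger of the absolute values being 0.0436. Vector reads counted at GPR20 and a response to SIGLEC6 cannot be told apart, since GPR20 counts did not depart from 1 ratio to SIGLEC6 in the 3 libraries (chi-square p = 0.14) and 28 counts leave that test little power.

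The third pattern is the set of 112 mostly small changes. The real grouping gave 112 genes and the highest of the other splits 5, with 1 of 10 splits as large, and 10 splits are too few for a share under 0.05. A trend with transcript length or GC content as the whole cause was argued against, since 107 of the 112 genes stayed past the threshold and 112 kept their direction with offsets for both. The offset fit was also the more permissive, with 388 calls and a common dispersion of 0.00211 against 0.00261. Log2 fold changes had a Spearman correlation of -0.19 with GC content and 0.0082 with length. A GC trend as part of the cause therefore stays open. Chance differences between separately selected cell populations and an effect of SIGLEC6 cannot be told apart, because the labels describe 1 kind of cells per group, and SIGLEC6 itself stays among the open explanations as untested. The columns name the controls shNC, so any difference between the vectors other than SIGLEC6 could not be separated from it either.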
